A study of Bacillus subtilis with 3 samples.

How the data were processed

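RNA of untreated and moenomycin-treated cells of 3 independent *B. subtilis* 168 cultures was compared on 3 two-colour arrays. Per the labels' protocols, cDNA was made from 20 µg of total RNA by indirect labelling, with the untreated sample in Alexa Fluor 555 and the treated sample in Alexa Fluor 647 on every array. Dyes were not swapped, so a gene-specific dye effect adds to the treatment effect. The deposited values are log2 ratios, 1 per array and feature, made by the authors. The base follows from the values: the largest ratios are log2 of whole numbers or of multiples of 0.5. The direction, treated over untreated, is likely from the sample titles and the design text and is not recorded with the values. The scanner, background correction, normalization and treatment of replicate spots are not given in the sources used here. Centring is not exact, since the medians over genes were 0.05, 0.12 and 0.02. Spot intensities were not used here, so that signal over background could not be measured, and genes near the detection limit were recognised from the ratios alone.

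The value table held 4116 features, of which 10 are *Escherichia coli* or BMV control features and 4106 are genes, with 1 feature per gene name. Both names listed for mdh, mdh and citH, were on the array, so 1 gene can have more than 1 feature. In the lists only the first name found was used. Controls were left out of all tests. Of the 4106 gene identifiers, 3036 (73.9%) matched a symbol of the reference gene table and 3113 did so when older names from the lists were added; the others kept the array's name. Values were used as deposited, with no further normalization or pseudocount. All 4106 genes had a value on at least 2 arrays. A value was taken as standing at the lower limit when its linear ratio or the inverse lay within 6e-05 (log2) of a multiple of 0.5, as a channel set to 1 would give. This reading comes from the values and no source states it. By chance 0.556% of values of 3 or more in size would meet it, and 89.5% did. Ratios at the limit have no measured value on one side, so no folds were drawn from them. The rule for named genes, fixed earlier, still picked its most extreme genes from among them, and their order is not read. A ratio of exactly 2, as sigM had on 1 array, meets the criterion too and cannot be told from an ordinary value.

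Mean log2 ratios were tested against 0 with limma (version 3.58.1, in R 4.3.3; lmFit with an intercept and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Each array pairs both portions of 1 culture, so the ratio is already paired. Gene lists were tested with camera in limma at an inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. At an estimated correlation camera uses the residual degrees of freedom, which are few with 3 arrays, so it can hardly call a list here. Its p-values, given beside the list calls, therefore do not show whether correlation between genes made a call. These tests ran over the 4100 genes with a value on all 3 arrays, with adjustment over the lists. Camera compares a list with the other genes, so that higher or lower there is relative to them, while fry compares a list with 0. The mean log2 ratio over genes was 0.79, 0.93 and 0.82 on arrays 1, 2 and 3. The difference between SigM and SigW members was tested by a two-sided permutation test over genes with 100000 resamples. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

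The groups, tests, 33 gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took the 12 most positive and 12 most negative called genes with the same sign on all 3 arrays, up to 4 called members per list (or, with none called, 2 as values), and a fixed set of genes for sigma factors, class A penicillin-binding proteins, lipid carrier recycling, the LiaRS and YtrA systems and flagellin. The lists came from general knowledge of *B. subtilis* regulons and pathways and covered sigma factor regulons, antibiotic-sensing systems, cell wall synthesis, stress responses, metabolism, translation, motility and development. Of their 604 members, 598 were matched to the array. rsiV was not matched, because its older name yrhM, which is on the array, was listed under sigV. The separate treatment of genes at the lower limit, the genes named because they lay above it, and 4 later lists were chosen after the values were seen. The 4 later lists are the ComA regulon, the yop genes, the PhoPR regulon and abundant transcripts outside translation.

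The procedure was tested on simulated data for this comparison, with 50 genes changed at each fold. Over 4100 genes, limma recovered 0% at 1.5-fold, 28% at 2-fold, 60% at 4-fold and 68% at 8-fold, with 6 false calls among 3900 unchanged genes. Over the 2840 genes never at the limit, it recovered 42%, 56%, 86% and 94%, with 6 false calls among 2640. A list of 30 genes shifted by 0.8 was called in both settings, and 0 of 30 unshifted lists were called by camera. The simulated genes were independent and, when unchanged, centred on 0. Real genes of a list can move together, with an estimated correlation of 0.593 for the SigB list. The simulation therefore does not measure false list calls under such correlation or beside the mostly positive genes at the limit. Its recovered shares and false calls are not rates for the real single-gene calls either. Over all genes, 3900 of 4100 simulated genes were unchanged, but limma gave 1101 higher and 871 lower real genes at an unadjusted p under 0.05. Benjamini-Hochberg adjustment depends on how many genes change. Of 439 real genes called lower, only 92 changed at least 2-fold, whereas the simulation recovered 0% at 1.5-fold. The alternatives were median centring, scaling, complete genes, leaving out each array, robust eBayes, array weights, stricter thresholds, other list tests, 1 value per run of neighbouring genes, and leaving out genes at or near the limit (multiples of 1/q with q up to 10).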

Results

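Transcript levels were measured with two-colour DNA microarrays in wild-type *Bacillus subtilis* 168 after a short exposure to moenomycin, a phosphoglycolipid antibiotic that blocks the glycosyltransferase step of peptidoglycan polymerisation. Each of 3 independent cultures was grown to mid-log phase (OD600 of 0.4) and divided, and one portion received moenomycin at 1 µg/ml for 15 min. Treated and untreated RNA of each culture were hybridised together, so that there were 3 arrays, 1 per biological replicate, and 1 comparison. The 3 arrays carried values for 4104, 4103 and 4105 of 4106 genes, and their number limits the precision. The median log2 ratio over genes was 0.05, 0.12 and 0.02 on arrays 1, 2 and 3. Positive values are read as higher with moenomycin. That direction is likely, from the order of the conditions in the sample titles and the design text, but it is not recorded in the value table itself.

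The comparison of treated with untreated cells asked which genes make up the moenomycin stimulon. Among genes with no ratio at the apparent lower limit of a channel, the SigM-controlled gene yqjL rose to a log2 ratio of 2.99 ± 0.25 (SD, n = 3), or 7.95-fold. murB, which encodes a cytoplasmic enzyme of peptidoglycan precursor synthesis, rose 5.68-fold (2.51 ± 0.36), and murG, the glycosyltransferase that makes lipid II, rose 4.19-fold (2.07 ± 0.16). In the opposite direction, srfAA, a surfactin synthetase gene, fell to −1.55 ± 0.11 and smc, whose product organises the chromosome, to −1.43 ± 0.06. Limma's moderated test called 679 genes higher and 439 lower of 4106 at an adjusted p under 0.05. Of the higher genes, 509 had on at least 1 array a ratio equal to log2 of a multiple of 0.5, as when one channel stands at a lower limit of 1, and only 170 were measured above that limit throughout. Of the lower genes, 418 were measured above it and 21 were not. Among the genes above the limit, 103 higher and 73 lower genes changed at least 2-fold. The criterion does not catch all residual background. The control feature Ecoli-ybaS, which holds no *B. subtilis* gene, had 0 arrays at the limit, with log2 ratios of 0.39, 3.23 and 0.11. A gene counted as above the limit can therefore still lie near background.

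Apart from yqjL and murB, the largest rises among genes above the limit were those of yxeL (3.64 ± 1.36), pksR of a polyketide synthase (3.11 ± 1.21), the sodium/proton antiporter gene nhaC (2.92 ± 1.09) and tuaF of teichuronic acid synthesis (2.71 ± 1.11; SD, n = 3). They were followed by ydcP (2.61 ± 0.32), hisA of histidine synthesis (2.57 ± 0.84), ydhM (2.55 ± 0.95), thiS of thiamine synthesis (2.52 ± 0.86), the phosphodiesterase gene phoD (2.46 ± 0.82) and yfiB (2.45 ± 0.63). The most negative log2 ratios were those of fabL, an enoyl-acyl carrier protein reductase gene (−2.12 ± 0.63), ycbN (−2.02 ± 0.60), yxaI (−1.74 ± 0.15), yopU (−1.72 ± 0.10) and sdpB (yvaX), which acts in maturation of the SDP cannibalism toxin (−1.71 ± 0.40). yvbI (−1.66 ± 0.14), yopM (−1.58 ± 0.26), yufK (−1.51 ± 0.18), yjcM (−1.42 ± 0.08) and yopO (−1.40 ± 0.27) also fell. Of these genes yxeL, tuaF and fabL lay near the limit on 2 arrays and ydcP, hisA and yfiB on 1, by a wider criterion, so that they drop out when genes near the limit are left out. The median SD of genes never at the limit was 0.20, below the SD of each of the rises from yxeL to yfiB. All of these genes had the same sign on 3 of 3 arrays, and limma's adjusted p lay between 0.00783 for yqjL and 0.0491 for tuaF. These 2 groups of 12 genes, srfAA and smc included, were chosen after the values were seen, because the fixed rule for named genes took its 24 most extreme genes from those at the limit.

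**Figure D1:**
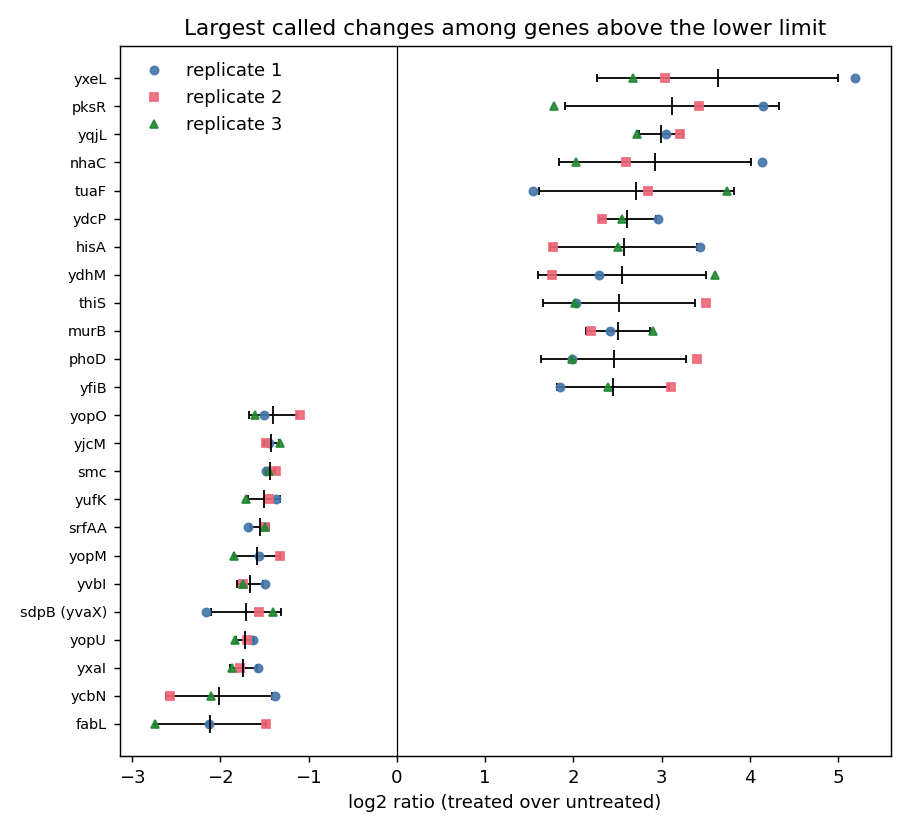
Log2 ratios (horizontal axis, treated over untreated) of the 12 most positive and 12 most negative called genes with no array at the lower limit. Symbols are the 3 arrays, vertical ticks the means and bars 1 SD; the means run from −2.12 for fabL to 3.64 for yxeL.

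By the fixed rule, the 12 most positive called genes were, in alphabetical order, dacF, ligB, the O-acetyltransferase gene oatA (yrhL, 5.98 ± 0.66; SD, n = 3), pgcM, spoIVFA (6.46 ± 1.00), uxaB, ybcM, ybgH, ycgS, yesR, ykvI and yorK. The 12 most negative were aspB, glcR, hemY of haem synthesis (−2.57 ± 0.63), the nucleoside phosphorylase gene pdp (−3.47 ± 0.80), the subtilosin gene sboA, xpt of purine salvage, yerA, yjbH (−3.27 ± 0.47), ykoV, ykrP, ynzC and ytrI. Each had at least 1 array at the lower limit, so the deposited log2 ratios are given without a fold, and their order carries no meaning. With all 1266 genes that touched the limit left out, limma called 349 higher and 761 lower of 2840. The median of these genes was −0.16; centring the arrays on them gave 463 higher and 427 lower calls. No single gene was called by limma in either direction without array 1 (807 and 359 genes at an unadjusted p under 0.05), and without array 2 or 3 there were 262 and 307 higher and 6 and 8 lower calls.

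**Figure D2:**
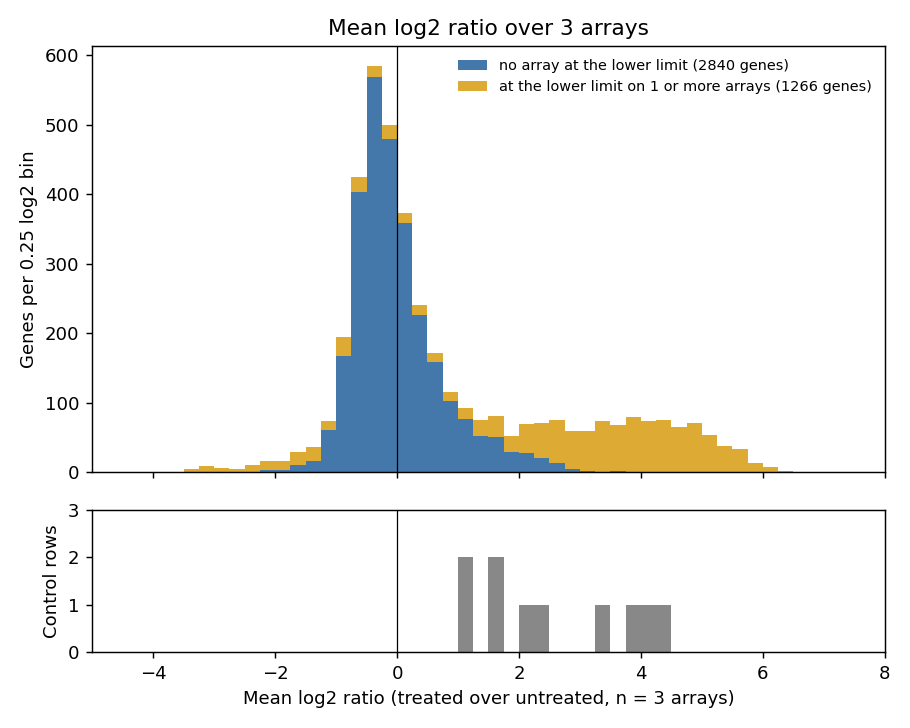
Number of genes (upper panel) and of control features (lower panel) by mean log2 ratio over 3 arrays, in bins 0.25 wide. The 2840 genes never at the lower limit (blue) centre on a median of −0.16, while the 1266 genes at the limit on 1 or more arrays (yellow) make up most of the values above 3, a range that some control features also reach.

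SigM, an extracytoplasmic function sigma factor for cell envelope stress, had the regulon that rose as a group. Of 37 measured members, 17 rose and none fell (22 and 0 at an unadjusted p under 0.05 in limma), with 21 higher when adjusted over the list alone. Besides yqjL and murB, ypbG rose 5.38-fold (2.43 ± 0.36), yebC 3.85-fold (1.94 ± 0.48), the lipoteichoic acid synthase gene yfnI 2.74-fold (1.46 ± 0.25) and amj (ydaH), for an alternate lipid II flippase, 2.26-fold (1.17 ± 0.35; SD, n = 3). mreB and mreC, for cell shape, rose 2.05-fold (1.04 ± 0.09) and 2.10-fold (1.07 ± 0.09), and minC of division site selection 1.76-fold (0.82 ± 0.14). The list median was 0.71, and camera in limma called the list higher with an adjusted p of 0.000381 (adjusted p = 0.517 with an estimated correlation). sigM itself stood at 0.71 ± 0.43, the undecaprenyl pyrophosphatase gene bcrC (ywoA) at 0.62 ± 0.42 and ponA, for the main bifunctional penicillin-binding protein, at 0.60 ± 0.23; these 3 did not pass the test (limma adjusted p = 0.101, 0.121 and 0.0640). ponA passed with genes at the lower limit left out (0.0334), and bcrC did so only after centring too (0.0755, then 0.0487).

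The regulon of SigW, the other large envelope stress sigma factor, fell as a group in camera (adjusted p = 0.000586; adjusted p = 0.517 with an estimated correlation). Of 50 members 7 fell and none rose (17 and 3 at an unadjusted p under 0.05 in limma), but no member passed when adjusted over the list alone. The median was −0.40. With genes at the lower limit left out 2 were higher and 17 lower, and after centring on the remaining genes 6 were higher and 7 lower, with a median of −0.24. yuaF (−1.12 ± 0.41), yobJ (−0.96 ± 0.09), ydbS (−0.91 ± 0.24) and yknW (−0.83 ± 0.19) fell, whereas sigW at −0.60 ± 0.31 was not called (limma adjusted p = 0.0866, 0.0490 with genes at the lower limit left out, and 0.106 after centring too). Members of the SigM list averaged 0.81 and those of the SigW list −0.30, a difference of 1.11 (two-sided permutation test over genes, p = 1e-05, the smallest value that 100000 resamples can give). Genes are not independent replicates; across the 3 arrays the difference was 1.11 ± 0.096 (SD, n = 3). The SigW call ended, at an adjusted p of 0.0550, when genes at the lower limit were left out, while the difference between the regulons was then 1.21.

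Of the remaining sigma factors of this family, sigX fell (−1.08 ± 0.06) and sigV rose 4.30-fold (2.10 ± 0.40). In the SigX regulon 1 of 19 members rose, dltE of the D-alanylation operon (0.96 ± 0.20), and 4 fell, among them yfhO (−0.81 ± 0.14) and tagU (lytR, −0.80 ± 0.14). Adjusted over the list alone the counts were 1 and 7 (camera adjusted p = 0.0924). In the SigV operon the 3 genes tested were called higher, but only sigV was measured above the lower limit. rsiV was left out, because its older name yrhM, present on the array, had been listed under sigV. For oatA (yrhL) and yrhK, at the limit, residual background is not excluded. Adjusted over the list alone the count was also 3 (camera adjusted p = 0.0545, 0.517 with an estimated correlation, and 0.0272 without array 2). Among the 7 genes for sigma factors of this kind, 2 were called higher and 1 lower, also when adjusted over the list alone. Of the 2, sigZ had ratios at the limit (5.53 ± 0.77). The list's median was 0.11 and its mean 0.89, whereas its camera test pointed down (adjusted p = 0.987).

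Cell wall synthesis genes moved in both directions. Among 19 precursor synthesis genes murB, murG and amj (ydaH) rose and uppS, for undecaprenyl pyrophosphate synthase, fell (−0.59 ± 0.13; SD, n = 3). Adjusted over the list alone, 3 were higher and none lower (3 lower at an unadjusted p under 0.05 in limma). None of the 4 class A penicillin-binding protein genes, the targets of moenomycin, passed limma's test (2 higher and 0 lower at an unadjusted p under 0.05), nor when adjusted over the list alone. ponA was the 1 gene that passed with genes at the lower limit left out. pbpD stood at −0.16 ± 0.17, pbpF at 1.61 ± 1.72 (0.71, 3.59 and 0.53 on the 3 arrays) and pbpG (ywhE), with 1 array at the limit, at 3.53 ± 1.97. Of 14 other penicillin-binding and SEDS protein genes, pbpA rose (1.20 ± 0.27) and dacF was called higher with ratios at the limit. There were 4 higher and 1 lower when adjusted over the list alone. In cell division and shape 6 of 18 genes were called higher, 1 of them at the limit, and 2 fell; divIB rose (1.21 ± 0.23). Adjusted over the list alone the counts were 7 and 3. The autolysin list of 14 genes also holds genes that do not encode autolysins, iseA and pdaC among them. Of its members lytH (yunA, 2.09 ± 0.53) rose, and lytA (−0.93 ± 0.10), pdaC (yjeA, −0.62 ± 0.13) and iseA (yoeB, −0.55 ± 0.10) fell. Adjusted over the list alone they did so too. The 3 falls are not read as a fall of autolysins. This list's median was −0.17 but its mean 0.23. Camera's adjusted p for these 5 lists was 0.695, 0.512, 0.512, 0.604 and 0.252. Fry, which compares a list with 0, gave adjusted p of 0.0401, 0.0215, 0.0526 and 0.0369 (up) and 0.0652 (down).

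In wall teichoic and teichuronic acid synthesis limma called 6 of 21 genes higher, and tagU (lytR) fell. Of the 6, tuaH (5.57 ± 1.89), tuaE (4.49 ± 0.43) and mnaA (yvyH, 2.16 ± 0.52) were at the lower limit, so that residual background is not excluded for these 3. The others were above it, among them tuaG (1.13 ± 0.23) and tuaF, which lay near it on 2 arrays. The counts adjusted over the list alone were 6 and 1 (camera adjusted p = 0.0924). Lipoteichoic acid synthesis had yfnI higher and yqgS lower (−0.50 ± 0.06; SD, n = 3) of 6 genes, 1 and 1 adjusted over the list alone (camera adjusted p = 0.252). With genes at the lower limit left out, camera called wall teichoic and teichuronic acid synthesis higher (adjusted p = 0.0202, and 0.0839 without array 3 as well; adjusted p = 0.561 with an estimated correlation).

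Among systems that sense cell wall antibiotics, bceA (ytsC) of the bacitracin transporter rose 2.85-fold (1.51 ± 0.55; SD, n = 3) and yxdL of a related module 2.82-fold (1.49 ± 0.32). In all, 4 of 13 genes of such modules were called higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.230). The other 2 higher genes, yxdM and yxeA, had ratios at the lower limit. In the YtrA regulon ytrE rose 1.42-fold (0.50 ± 0.03) as the only called gene of 9. No gene of the list passed when adjusted over the list alone (4 higher and 0 lower at an unadjusted p under 0.05 in limma). ytrA stood at −0.47 ± 0.42 and ywoB at 1.63 ± 1.11, not called. With genes at the lower limit left out, camera called this regulon higher (adjusted p = 0.0416 against 0.296 over all genes, and 0.0619 without array 2 as well; adjusted p = 0.561 with an estimated correlation). No gene of the LiaRS operon was called of 6 by limma, nor when adjusted over the list alone (2 higher and 1 lower at an unadjusted p under 0.05). liaI (yvqI) stood at 0.47 ± 0.11 and liaH (yvqH) at 0.65 ± 0.27 (camera adjusted p = 0.683). Both were called higher with genes at the lower limit left out (limma adjusted p = 0.0298 and 0.0358), and liaG (yvqG, −0.33 ± 0.05) lower (0.0468); after centring too, liaG was not (0.190).

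Genes for growth and motility fell as groups. Of 49 ribosomal protein genes 23 fell and none rose (37 and 0 at an unadjusted p under 0.05 in limma), with 34 lower when adjusted over the list alone. The median was −0.59, and rpmD (−1.15 ± 0.23), rplF (−1.09 ± 0.18) and rpsN (−0.95 ± 0.22; SD, n = 3) were among the lower genes. Of 47 flagellar and chemotaxis genes 19 fell, among them flgB (−0.96 ± 0.20), flgC (−0.94 ± 0.09), cheY (−0.91 ± 0.15) and the flagellin gene hag (−0.66 ± 0.11), and the chemoreceptor gene tlpA rose (1.56 ± 0.47). Adjusted over the list alone 30 were lower and 1 higher. Of 9 ATP synthase genes 5 fell, with atpB at −1.09 ± 0.40 and atpA at −0.90 ± 0.03, 6 when adjusted over the list alone. Of 14 genes of the citric acid cycle 5 fell, among them odhA (−0.77 ± 0.05), odhB (−0.71 ± 0.11), sucD (−0.71 ± 0.10) and citB (−0.59 ± 0.11), 6 when adjusted over the list alone. Camera called these 4 lists lower, with adjusted p of 4.92e-11, 1.93e-07, 0.00208 and 0.00694 (adjusted p = 0.517, 0.517, 0.517 and 0.544 with an estimated correlation). The 4 calls held with genes at the lower limit left out, though that of the citric acid cycle ended without array 2 as well (adjusted p = 0.0619). After centring on the remaining genes, whose median lay at −0.16, the list medians were −0.43, −0.45, −0.41 and −0.41. Treated RNA carried the same dye on every array, so that a dye effect of a gene cannot be separated from the treatment here.

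Camera called 3 further lists lower, and none of the 3 calls held with genes at the lower limit left out (adjusted p = 0.0831, 0.106 and 0.161; for FapR 0.0491 after centring too). In fatty acid synthesis under FapR, accD (−0.83 ± 0.20; SD, n = 3) and accA (−0.80 ± 0.11) fell of 14 genes, 2 when adjusted over the list alone (camera adjusted p = 0.0130; adjusted p = 0.583 with an estimated correlation). In pyrimidine synthesis pyrR (−1.14 ± 0.31) and pyrB (−0.54 ± 0.05) fell of 10, 2 when adjusted over the list alone. Camera's adjusted p for pyrimidine synthesis was 0.0162 (adjusted p = 0.517 with an estimated correlation). That estimate was −0.107, below the fixed 0.01, so the lost call cannot be ascribed to correlation between its genes. At an estimated correlation camera tests on the few residual degrees of freedom of 3 arrays, where hardly any list can be called. ATP synthase, with an estimate of 0.0126, lost its call too. In the Fur iron uptake regulon none of 29 genes was called by limma, nor when adjusted over the list alone (0 higher and 9 lower at an unadjusted p under 0.05; camera adjusted p = 0.0153, and 0.0917 without array 2; adjusted p = 0.689 with an estimated correlation). Limma called 8 Fur genes lower with genes at the limit left out, among them yfiZ (−0.48 ± 0.07), and after centring too none was. dhbF stood at 2.11 ± 1.56, with 2 arrays at the limit, and dhbC at −0.80 ± 1.95. Purine synthesis had 6 of 15 genes lower, among them purA (−0.97 ± 0.16) and guaA (−0.71 ± 0.19) and 1 gene at the limit. Adjusted over the list alone, 1 was higher and 6 lower (camera adjusted p = 0.107, 0.706 with an estimated correlation, and 0.0336 without array 1). Branched-chain amino acid synthesis had ilvA lower (−0.64 ± 0.13) of 11, none when adjusted over the list alone (0 higher and 3 lower at an unadjusted p under 0.05 in limma). Camera's adjusted p for it was 0.0568, 0.583 with an estimated correlation, and 0.0197 without array 3.

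Of the 10 genes of the Spx thiol stress list, the oxidoreductase gene nfrA (1.10 ± 0.05; SD, n = 3) and the thioredoxin system genes trxB (0.79 ± 0.12) and trxA (0.76 ± 0.12) rose. yjbH, for the adaptor that delivers Spx to proteolysis, was called lower with ratios at the lower limit. For this list 3 were higher and 2 lower when adjusted over the list alone. Camera called the list higher with genes at the limit left out (adjusted p = 0.0327 against 0.534 over all genes; adjusted p = 0.561 with an estimated correlation). The general stress regulon of SigB had 1 of 48 genes higher, aldY at the limit, and 4 lower, among them dps (−0.96 ± 0.31) and ywsB (−0.86 ± 0.21). No SigB gene passed when adjusted over the list alone (2 higher and 12 lower at an unadjusted p under 0.05 in limma). The list's median was −0.28 but its mean 0.19. Camera's adjusted p was 0.0568 (0.727 with an estimated correlation, over all arrays). It was 0.00147 without array 2, whose list mean of 0.79 stood against 0.12 and −0.33 on the others.

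Among other stress lists, lonA fell (−0.56 ± 0.05; SD, n = 3) of 14 heat shock chaperone and protease genes (camera adjusted p = 0.0600), and katA (−0.77 ± 0.23) and hemA (−0.61 ± 0.09) fell of 10 peroxide stress genes (camera adjusted p = 0.0568). No gene of either list passed when adjusted over the list alone (1 higher and 3 lower, and 0 higher and 6 lower, at an unadjusted p under 0.05 in limma). No gene of 5 in the CssRS secretion stress list was called by limma or when adjusted over the list alone (1 higher at an unadjusted p under 0.05; camera adjusted p = 0.667); cssR stood at 0.42 ± 0.33. The protease gene htrC (yyxA, 0.41 ± 0.10) was called higher with genes at the lower limit left out (limma adjusted p = 0.0372). Of 16 genes of the LexA DNA damage response recA (−0.69 ± 0.12) and ruvB (−0.59 ± 0.04) fell, while yneB rose (0.95 ± 0.28) and uvrX was called higher with ratios at the lower limit. The LexA counts adjusted over the list alone were also 2 and 2, with a median of −0.10 and a mean of 0.54 (camera adjusted p = 0.604).

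Lists for development held many genes at the lower limit: 11 of 18 in competence, 10 of 19 in cannibalism and early sporulation under Spo0A, and 6 of 20 in the biofilm matrix. In competence 5 genes were called higher, 4 of them with ratios at the limit, such as comGA (4.43 ± 0.77; SD, n = 3) and comC (4.03 ± 1.54), and comFA above it (1.54 ± 0.33). comS, a gene nested in the surfactin operon, fell (−0.54 ± 0.02). The counts adjusted over the list alone were 5 and 1 (camera adjusted p = 0.145). In the Spo0A list 5 genes were called higher, all with ratios at the limit, including sigE (4.65 ± 1.03) and skfB (ybcP, 5.66 ± 0.62). Of the others 4 fell, including spo0A (−0.95 ± 0.03), sdpB (yvaX) and the immunity gene sdpI (yvaZ, −1.14 ± 0.40). Adjusted over the list alone 5 were higher and 5 lower (camera adjusted p = 0.682). Among its 9 genes above the limit, tested without those at the limit, none were higher and 6 lower in limma, with a median of −0.88 and a camera test that pointed down (adjusted p = 0.244). No biofilm matrix gene was called by limma or when adjusted over the list alone (3 higher and 0 lower at an unadjusted p under 0.05; camera adjusted p = 0.759); epsF (yveP) stood at 3.40 ± 2.17 and epsJ (yveT) at 3.14 ± 2.25, each with 1 array at the limit. epsH (yveR, 1.30 ± 0.69) was called higher when genes at the limit were left out (limma adjusted p = 0.0415).

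**Figure D3:**
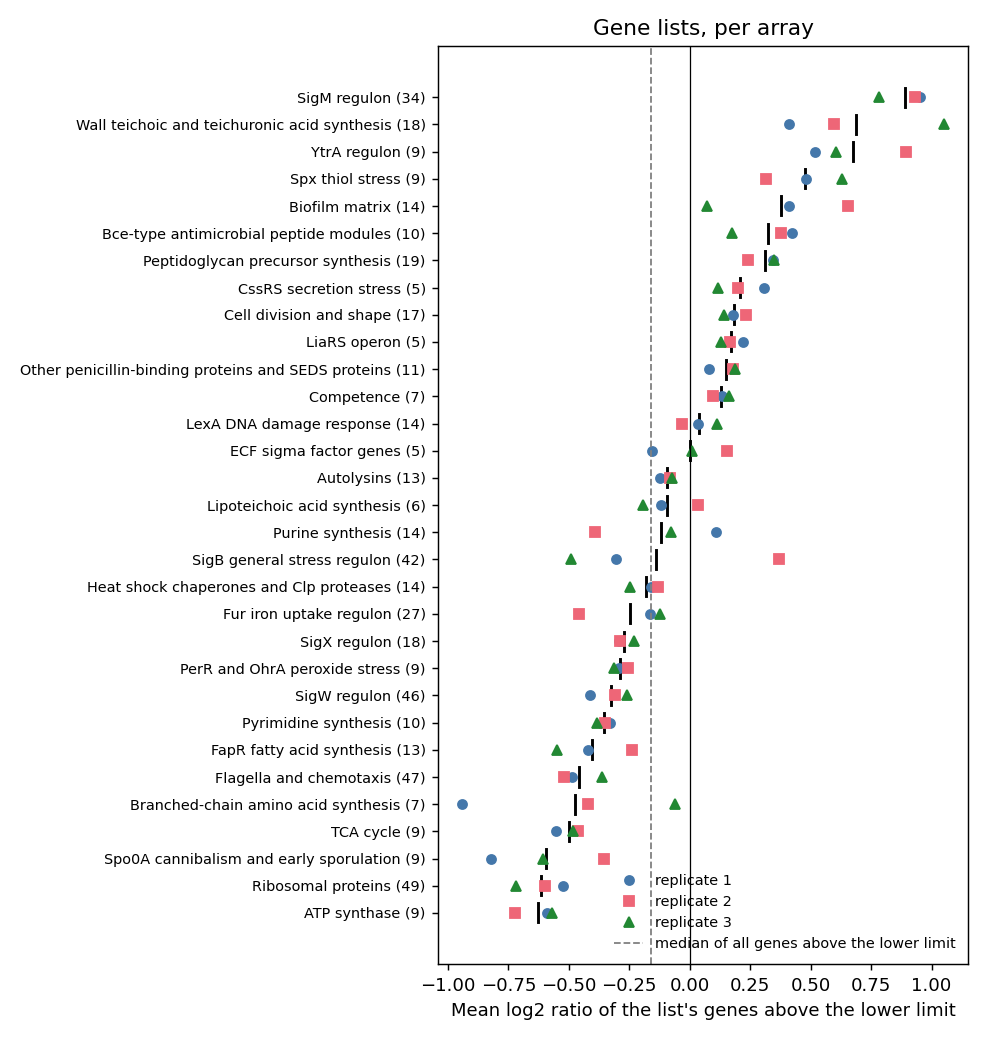
Mean log2 ratio (horizontal axis, treated over untreated) of each gene list with at least 5 members never at the lower limit; the number of such members stands beside each name. Symbols are the 3 arrays, black bars the means, and the dashed line the median of all 2840 such genes, −0.16. The SigM regulon lies highest, at 0.89, and ribosomal proteins and ATP synthase lowest.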

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

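All tests in this part were chosen after the result was seen.

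The 10 control features, which hold no *B. subtilis* gene, gave a signal outside the comparison: their 30 values had a median log2 ratio of 2.84, between 0 and 6.28, with 25 above 0 and none below. Large positive ratios of genes had the same form. Of 2302 values of 3 or more in size, 89.5% were log2 of a multiple of 0.5, as 23 of the 30 control values were, which is consistent with one channel at a lower limit of 1 and residual background in the treated channel. Induction of the genes by moenomycin stays open. Of 529 genes at the limit on all 3 arrays with a mean above 0, 48.8% had a mean above the highest control mean of 4.26. That share does not decide the question, since such ratios follow the level of the other channel, which can differ between features. Residual background and induction cannot be told apart gene by gene here, because only ratios were used and no channel's own level. Genes above the limit are not free of this doubt, since the control feature Ecoli-ybaS had 0 arrays at the limit (0.39, 3.23 and 0.11).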

How the results depend on the processing

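The settings that treat genes at the lower limit separately, and their tests, were chosen after the result was seen, as was the test of called genes over sign patterns. The 3 arrays allow 4 sign patterns, too few for a share under 0.05: 1 pattern of 4, the real one, gave as many called genes (1118; highest other 0) and 1 of 4 as many called lists (9; highest other 7). With genes at the limit left out, 3 of 4 patterns gave as many called lists (8; highest other 8), so that patterns with 1 array turned called as many lists as the real one. The difference between SigM and SigW kept its direction and its side of the threshold under every alternative run, from 1.05 without array 1 to 1.44 with genes at the limit left out and 1 value per run. Counts of called genes stayed within 1.5 times the first count under median centring, scaling, complete genes, robust eBayes and array weights. Of the 190 genes run through the alternatives, only dhbC changed sign. Genes named only from later lists were not run. srfAB had 1 array above 0 and 2 below. Single-gene calls moved most with the number of arrays: leaving out 1 array gave 0 to 307 higher and 0 to 8 lower genes (limma; without array 1, 807 and 359 at an unadjusted p under 0.05), with 2 arrays leaving fewer degrees of freedom. With genes at the limit also left out it gave 0 and 0 each time (354 to 439 higher and 676 to 788 lower at an unadjusted p under 0.05). An absolute log2 ratio of at least 1 left 611 higher and 92 lower genes, of which 103 and 73 had no ratio at the limit. An adjusted p under 0.01 left 139 higher and 0 lower in limma (871 lower at an unadjusted p under 0.05). Leaving out genes at the limit gave 349 higher and 761 lower genes, and leaving out those near it too gave 346 and 820; fewer genes were then tested, with a smaller spread. With arrays centred on the remaining genes, 52.0% of calls were higher, against 31.4% without that centring (48.0% and 68.6% if the ratios run the other way).

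List calls depend on the list test: camera with an estimated correlation called 0 lists higher and 0 lower, against 1 and 8 (fry, 12 and 10). Median centring or scaling called 2 lists higher. Leaving out 1 array called 1 to 2 higher. Without genes at the limit 4 lists were higher and 4 lower, with centring 4 and 5, without genes near the limit 4 and 4, and with 1 array also left out 3 to 4 and 4 to 5. Some list tests changed direction, each with an adjusted p above 0.05 except LexA with fry. Camera sets a list against the other genes and fry against 0, so that changes with fry can come from this. The cause of the other changes was not tested. ECF sigma factor genes did so with fry (adjusted p = 0.162), without shared members (0.763), with centring (0.967), with scaling (0.935) and without array 1 (0.890). Peptidoglycan precursor synthesis (0.759) and cell division and shape (0.482) did so without shared members. LexA did so with fry (0.0401), with genes at the limit left out and centring (0.992), without genes near the limit (0.967), and without genes at the limit and array 2 (0.823), as did purine synthesis in that last setting (0.823). Competence did so without genes near the limit (0.942). Spo0A did so without genes at the limit (0.244), with centring too (0.165), without genes near the limit (0.267), and without genes at the limit and any 1 array (0.150 to 0.302). Over all settings with 1 array left out, most of which kept the direction, the adjusted p ranged from 0.622 to 0.963 for ECF, from 0.640 to 1.00 for LexA, from 0.0336 to 0.823 for purine synthesis, whose lowest value was called lower, and from 0.150 to 0.821 for Spo0A. dhbC lay between −1.78 without array 1 and 0.17 without array 2, against −0.80.

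No paired analysis was possible because there is 1 group of ratios and each array already pairs both portions of a culture. A median over features of a gene was not run, since each gene name has 1 feature. The features of mdh and citH, listed as names of 1 gene, were not combined. A filter on low intensities was not run either, since no intensities were used here. Signal over background, which arrays are limited by, was therefore not measured.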

Other observations

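The tests of the ComA, PhoPR and yop lists and those without genes at the lower limit were chosen after the result was seen. Leaving out each array and taking 1 value per run of neighbouring genes were planned, and the dye test on abundant transcripts was set out before its value was seen.

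Many genes of quorum sensing under ComA were lower. Of 11 members of the ComA quorum sensing regulon measured above the lower limit, 8 were called lower by limma among genes above the limit and none higher, with a median of −0.89. Besides srfAA, rapF stood at −1.36 ± 0.24, phrF at −0.97 ± 0.19, phrA at −0.89 ± 0.19 and rapA at −0.78 ± 0.21 (SD, n = 3). Camera gave an adjusted p of 0.00176 over 3 lists (adjusted p = 0.363 with an estimated correlation), and 3 of 3 arrays had a negative mean. Of the surfactin synthetase genes only srfAA was called; srfAB stood at −0.26 ± 0.89 (1 array at the limit), srfAC at −1.04 ± 0.61 and srfAD at −1.42 ± 1.43. comS belongs to this list and to competence. A hypothesis is that moenomycin may lower ComA-dependent transcription; the list was drawn up after srfAA and rapF had been seen. Without both, camera's adjusted p was 0.0121 over 9 members (adjusted p = 0.288 with an estimated correlation). However, these include srfAC and srfAD of the surfactin operon, comS nested in it, and phrF, next to rapF. Without both operons 5 members were left, 4 of them lower, with an adjusted p of 0.0790 (adjusted p = 0.524 with an estimated correlation), so that a lower level of the regulon as a group stays open.

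Phosphate starvation genes gave no call independent of the genes that prompted the list. Of 12 members of the PhoPR regulon above the limit, 7 were called higher and 2 lower by limma, with a median of 1.11; camera gave an adjusted p of 0.00976 (adjusted p = 0.391 with an estimated correlation). phoD stood at 2.46 ± 0.82, tuaG at 1.13 ± 0.23 and phoA at 1.08 ± 0.47 (SD, n = 3). In contrast, the regulator genes phoP and phoR stood at −0.27 ± 0.22 and −0.64 ± 0.20 and glpQ at −1.37 ± 0.77. By the wider criterion glpQ lay near the limit on all 3 arrays. 9 more members, among them pstS and pstC, had ratios at the limit. The list holds 8 tua genes of the wall teichoic and teichuronic acid list. The list was drawn up after phoD and tua genes had been seen; without them 5 members were left, 2 higher and 2 lower, with a median of −0.27 and an adjusted p of 0.868 (camera). A higher level of the regulon as a group stays open.

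Whether the yop genes of the SP-beta prophage moved as a group stays open. Of 22 genes above the limit, 10 were called lower, from yopK to yopU in the order of their names where measured above the limit, and 3 higher, yopB (1.15 ± 0.38), yopD (0.71 ± 0.32) and yopX (1.24 ± 0.61; SD, n = 3). Camera's adjusted p of 0.0838 missed the threshold set for a lower level of the whole group (0.0180 over all genes; 0.0207 after centring; 0.520 without yopU, yopM and yopO, which prompted the list; adjusted p = 0.583 with an estimated correlation). A missed threshold does not show that the group was level, and the values differ between settings.

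Leaving out genes at the lower limit argues against that limit as the source of the SigM rise, since camera's adjusted p was then 1.55e-10 (adjusted p = 0.561 with an estimated correlation). A single operon could not account for it either: with 1 value per run of neighbouring genes, the difference from the SigW list was 1.26. Leaving out each array in turn kept the difference between 1.05 and 1.15. A dye effect on the SigM genes stays open, as dyes were not swapped, and so does an effect of moenomycin, which the design names.

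For the lower ribosomal protein, ATP synthase and flagellar lists, a dye effect on abundant transcripts could be the source. It would also lower abundant transcripts outside translation. The 22 such genes had a median of −0.41 with an SD of 0.35, above the ribosomal median of −0.59 by 0.171, which is less than that SD. The SD is that of single genes and not of their median, so this comparison could hardly separate the lists. The dye effect and the treatment cannot be told apart for these lists, because every array had the same dye orientation. Only 3 of the 22 lay above the median of all genes never at the limit.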
